A study of Mus musculus with 12 samples.

How the data were processed

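The deposited table held raw counts per gene for 12 mouse liver libraries, made by the authors. Per the submitters' processing notes, the tools named were Trimmomatic, HISAT2 2.0.4, SAMtools, featureCounts and DESeq2 with the mm10 build, with no roles or order, and the gene annotation and strand setting are not given in the sources used here. Per the labels' protocols, RNA was isolated with a Bio-Rad column kit and libraries were made with a stranded Illumina mRNA kit. The authors' deposited counts were whole numbers with no normalization. All 54838 identifiers named a gene, 54723 had a symbol, and no summary lines were present. The groups were taken from the labels: 21% or 7% O2 for 24 h, PBS or DEX at 10 mg/kg, 2 h after injection, 3 biological replicates each. The labels' protocol calls both oxygen arms the hypoxia group, which was read as a slip because the titles name normoxia. All 12 libraries had Xist above 517 CPM and 0 counts over 4 Y-linked genes.

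The tests, lists, naming rule and alternatives were fixed before the data were examined. Exceptions are the alternatives described as added and the tests described below as chosen after the result was seen. Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the groups, which left 13861, and scaled with TMM. A quasi-likelihood model (estimateDisp, glmQLFit with robust estimation, glmQLFTest) with 1 mean per group over all 12 libraries gave 8 residual degrees of freedom. The comparisons were hypoxia against normoxia in PBS mice, DEX against PBS at each oxygen level, the difference of these DEX responses (the interaction), and hypoxia against normoxia in DEX mice. Benjamini-Hochberg adjustment ran over all tested genes per comparison, and an adjusted p under 0.05 was the threshold. Expression is given as CPM on TMM-scaled library sizes, and log2 CPM for list tests and components used a prior count of 2. Components used the 1000 most variable genes. Every adjusted p called edgeR's is from this model, and every SE is that of its log2 fold change.

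In all, 31 gene lists with 633 members, 572 of them measured, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted by Benjamini-Hochberg over 124 tests, the 31 lists in 4 comparisons. Each call was repeated with the correlation estimated per list, and all 28 calls were lost there. Of the genes in the lists, 25 belong to more than 1 list. Genes named in the text are those with the 6 largest rises and 6 largest falls among called genes of at least 5 CPM in 1 group whose groups do not overlap (no such condition for the interaction), leaving out clone, major urinary protein and immunoglobulin names, up to 3 members per list, and a fixed set of 20 glucocorticoid, metabolic and hypoxia genes. Of that set Car9 was not tested because of the count filter, and G6pc1 is a synonym of G6pc. Results for some named genes are not reported here. The genes drawn or given per library were chosen after their values were seen. Positions are from GENCODE release M21 on the mm10 build and matched 13858 of the tested genes. Without a stated strand setting, overlapping genes and near-identical copies such as Cyp4a12a and Cyp4a12b can share reads.

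Depth ranged from 12464687 to 24715995 counts per library. A fold against a group without counts used a floor of 3 counts per library and covers counting error only. On simulated counts with 200 changed genes in Hypoxia_DEX (13812 genes in the fit), the comparison of DEX against PBS in hypoxia recovered 35.8%, 85.1% and 97.0% of genes changed 1.5-, 2- and 4-fold, and the interaction 11.9%, 64.2% and 92.4%. False calls were 6 of 151 and 6 of 118. On simulated counts camera found 2 of 2 shifted lists and 0 of 28 unshifted ones. Genes were drawn independently there, so this does not test calls in lists whose genes are correlated. Replicates were compared pairwise by the chi-square of their counts against sampling noise, over genes with at least 10 reads.

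Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, the replicate number as a block, only the groups compared in the fit, an estimated correlation for lists, and leaving out each library. After seeing the data, 3 were added: Hypoxia_DEX-1 and Hypoxia_DEX-3 summed into 1 library, Hypoxia_DEX-2 and Hypoxia_PBS-1 left out together, and, for the interaction counts alone, that pair summed with Hypoxia_DEX-2 left out, where the 1 library is assumed to vary like the other groups. Other splits of the libraries were refitted, 10 per comparison of 3 against 3 and 100 drawn for the interaction. Overlap from shared controls was simulated 50 times for unchanged groups. Figures were drawn with matplotlib 3.10.9.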

Results

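Liver mRNA was sequenced from C57BL/6J mice in a design that crossed oxygen with dexamethasone (DEX), a synthetic ligand of the glucocorticoid receptor. Mice breathed either 21% O2 or 7% O2 for 24 h, were injected with PBS or with DEX at 10 mg/kg, and were sampled 2 h later. The 4 groups, Normoxia_PBS, Normoxia_DEX, Hypoxia_PBS and Hypoxia_DEX, held 3 libraries each. Total counts per library ranged from 12464687 to 24715995, and 13861 of the 54838 gene identifiers entered the tests. Expression values are means of CPM, read counts scaled to library size, ± SD over n = 3 libraries unless stated. The series title names the effect of hypoxia on glucocorticoid receptor function as the subject, so the comparisons ask what hypoxia changed, what DEX changed at each oxygen level, and where the DEX response differed between them.

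Oxygen and DEX were the main axes of variation. The first principal component held 49.2% of the variance and separated the hypoxia from the normoxia libraries, and the second held 32.9% and separated DEX from PBS. On the second component Hypoxia_DEX-2 scored 9.22, against 21.52 and 21.39 for the other Hypoxia_DEX libraries, and Hypoxia_PBS-1 scored -6.36, against -25.48 and -22.24. Hypoxia_DEX-1 and Hypoxia_DEX-3 were far closer to each other than any other pair of replicates. Their counts differed by 1.79 chi-square units per gene, against 10.54 to 38.45 in the other pairs of replicates. In this pair 9.16% of genes exceeded the 5% limit of sampling noise, against 22.73% to 42.37%. The pair differed by more than sampling noise and was kept as 2 animals, as the design states. If the pair came from 1 animal, the standard errors of comparisons that use Hypoxia_DEX are too small. Counts with the pair summed into 1 library are therefore given beside them. The spread of each gene is estimated over all 12 libraries, so the other comparisons can be affected too. With the pair summed, 4732 genes were called for hypoxia under PBS, against 4953, and 2138 for DEX in normoxia, against 2326.

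**Figure D1:**
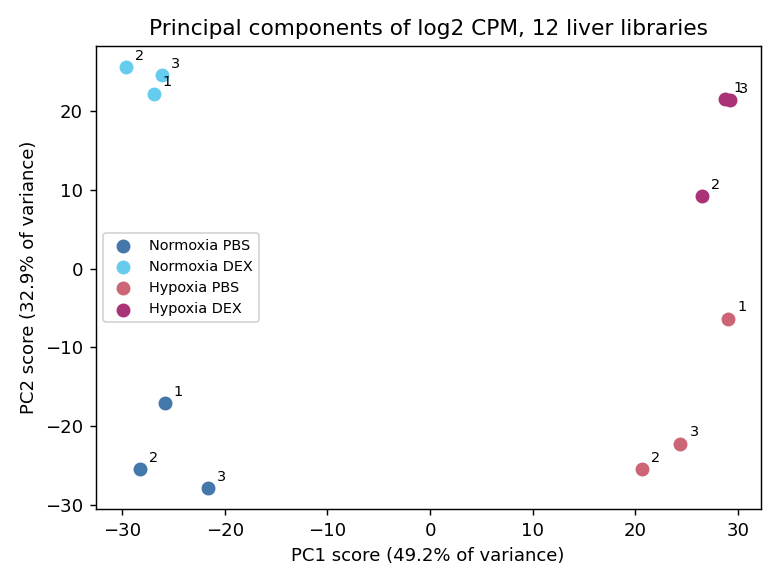
Scores of the 12 liver libraries on the first and second principal components of log2 CPM, with replicate numbers beside the points and colours for the 4 groups. Hypoxia_DEX-1 and Hypoxia_DEX-3 lie almost on top of each other, at 28.7 and 29.24 on the first component.

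Hypoxia alone was compared between the PBS groups. In hypoxia 11 of 19 glycolytic, 17 of 30 fatty acid oxidation, 25 of 30 oxidative phosphorylation and 26 of 30 ribosomal protein genes rose, while 20 of 24 interferon-stimulated genes and 14 of 15 Kupffer cell markers fell. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2618 genes were higher and 2335 lower in hypoxia, and 668 and 652 of them changed at least 2-fold. Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), the estrogen sulfotransferase, had the largest rise among the genes named by the fixed rule, from 0.599 ± 0.350 CPM to 79.0 ± 48.0 CPM (log2 fold change 7.08, SE 0.81, edgeR adjusted p = 0.000284). Apoa4, an apolipoprotein, rose from 107 ± 23.4 CPM to 2292 ± 669 CPM (log2 fold change 4.42, SE 0.26, edgeR adjusted p = 1.54e-06). Aqp8 (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004), a water channel, had the largest fall, from 137 ± 8.96 CPM to 9.61 ± 3.52 CPM (log2 fold change -3.84, SE 0.23, edgeR adjusted p = 1.77e-06). Ccnd1, which encodes cyclin D1, fell from 105 ± 17.7 CPM to 8.91 ± 1.22 CPM (log2 fold change -3.55, SE 0.25, edgeR adjusted p = 4.44e-06).

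Among the other leading genes, the sarcomere gene Myom3 rose by 6.69 on the log2 scale (edgeR adjusted p = 2.77e-05) and Cidec, a lipid droplet gene, by 5.16 (edgeR adjusted p = 0.00515). Treh, which encodes trehalase, rose by 4.71 (edgeR adjusted p = 3.33e-06) and the phosphodiesterase gene Pde6c by 4.43 (edgeR adjusted p = 3.35e-06). Log2 fold changes were -3.68 for Selenbp2 (edgeR adjusted p = 1.89e-05) and -3.64 for the aldehyde dehydrogenase gene Aldh3b3 (edgeR adjusted p = 4.63e-06). They were -3.22 for the fatty acid-binding protein gene Fabp5 (edgeR adjusted p = 0.000532) and -3.19 for Adgrf1 (edgeR adjusted p = 8.72e-06). Of the fixed glucocorticoid and hypoxia genes, Fkbp5 rose by 1.32, Per1 by 0.83, Angptl4 by 1.51 and Egln3 by 0.94 (edgeR adjusted p = 0.00277, 0.00146, 0.00384 and 0.00875). Pck1, which encodes the gluconeogenic enzyme PEPCK, fell from 1434 ± 452 CPM to 713 ± 94.2 CPM (log2 fold change -1.01, edgeR adjusted p = 0.0036). The glucocorticoid receptor gene Nr3c1 had a log2 fold change of 0.14 and did not pass (edgeR adjusted p = 0.146). Vegfa at 0.08, Slc2a1 at -0.27, Tsc22d3 at -0.33, Tat at -0.28, G6pc at 1.21, Cpt1a at 0.52, Cyp7a1 at 0.69, Mt2 at -0.30 and Hamp at 0.14 did not pass either, with edgeR adjusted p from 0.057 to 0.641. Cpt1a passed with DESeq2 and with the replicate number as a block (adjusted p = 0.0304 and 0.0225, from 0.00327 to 0.271 over all alternatives). It also passed without Hypoxia_PBS-2 or Normoxia_PBS-1, and so did Slc2a1 without Hypoxia_PBS-2 (adjusted p from 0.0401 to 0.577 over all alternatives). Lcn2 rose by 1.27 (edgeR adjusted p = 0.0373). The Lcn2 call was lost without Hypoxia_DEX-3, Hypoxia_PBS-2, Hypoxia_PBS-3, Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-1 or Normoxia_PBS-2, and without the count filter or with only the compared groups in the fit (adjusted p from 0.00419 to 0.114 over all alternatives). Fgf21 varied widely within groups and had a log2 fold change of -0.05 (edgeR adjusted p = 0.979), which became 3.59 (edgeR adjusted p = 0.0236) without Normoxia_PBS-1.

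Several lists of energy metabolism moved up in hypoxia with camera's preset correlation, and none of them passed with an estimated one. Of 25 measured targets of hypoxia-inducible factor (HIF), 9 rose and 2 fell, with a list median of 0.48 (camera adjusted p = 0.0234, adjusted p = 0.889 with an estimated correlation). Bnip3, a mitophagy receptor gene, rose by 1.33 ± 0.09 (SE) and Pdk1, a kinase that restrains pyruvate dehydrogenase, by 1.08 ± 0.08 (SE). In glycolysis, 11 of 19 rose and 2 fell (camera adjusted p = 0.0045, adjusted p = 0.771 with an estimated correlation). Gpi1 rose by 1.58 ± 0.10 (SE) and Eno1 by 1.46 ± 0.10 (SE). In fatty acid oxidation and ketogenesis, 17 of 30 rose and 2 fell, or 18 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000121, adjusted p = 0.9 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose in 25 of 30 cases with none lower, at a median of 0.39 (camera adjusted p = 2.09e-10, adjusted p = 0.891 with an estimated correlation). Of these, 0 were lower at an unadjusted p under 0.05 or by DESeq2. Atp5a1 rose by 0.63 ± 0.07 (SE) and Cox7b by 0.62 ± 0.07 (SE). Of 10 mitochondrially encoded genes, 6 rose (camera adjusted p = 0.00483, adjusted p = 0.891 with an estimated correlation). Of 30 cytosolic ribosomal protein genes, 26 rose, at a median of 0.31 (camera adjusted p = 2.38e-09, adjusted p = 0.889 with an estimated correlation). Of the 17 circadian clock genes, 9 rose and 1 fell (camera adjusted p = 0.00286, adjusted p = 0.889 with an estimated correlation). Cry1 rose by 1.74 ± 0.16 (SE).

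Interferon and macrophage transcripts were lower in hypoxia. Of 24 interferon-stimulated genes, 20 fell, or 22 adjusted over the list alone, at a median of -1.003 (camera adjusted p = 2.57e-08, adjusted p = 0.891 with an estimated correlation). Ifi44 fell from 6.70 ± 0.585 CPM to 1.27 ± 0.349 CPM (log2 fold change -2.41, SE 0.29, edgeR adjusted p = 5.33e-05). Of 15 markers of Kupffer cells, the resident macrophages of the liver, 14 fell, at a median of -1.24 (camera adjusted p = 2.96e-09, adjusted p = 0.889 with an estimated correlation). Clec4f fell from 113 ± 17.1 CPM to 25.9 ± 5.61 CPM (log2 fold change -2.13, SE 0.18, edgeR adjusted p = 1.08e-05). The log2 fold changes were -2.25 for Folr2 (edgeR adjusted p = 1.68e-06) and -1.27 for C1qa (edgeR adjusted p = 5.76e-06). Lymphocyte markers fell in 5 of 14 cases (camera adjusted p = 0.0252, adjusted p = 0.891 with an estimated correlation), or 3 by DESeq2. The lymphocyte call was lost without Normoxia_PBS-2 (adjusted p = 0.0557). Stellate cell and fibroblast markers fell in 6 of 14 cases and rose in 1 (camera adjusted p = 0.0155, adjusted p = 0.891 with an estimated correlation). The stellate cell call was lost without Normoxia_PBS-3 (adjusted p = 0.0535). The collagen gene Col3a1 dropped by 2.18 (edgeR adjusted p = 1.04e-07). Endothelial markers fell in 9 of 14 cases and rose in 2, cholangiocyte markers fell in 3 of 9, and neutrophil and erythroid markers rose in 1 of 9 and 2 of 8. Medians were -0.35 for 14 endothelial, -0.56 for 9 cholangiocyte, 0.40 for 9 neutrophil and 0.49 for 8 erythroid markers. None of these lists passed camera (adjusted p = 0.072, 0.321, 0.564 and 0.311). Only 1 of the 15 pancreatic acinar genes was measured, at -0.56. Inflammatory cytokine and NF-kB target genes had a list median of 0.51, but edgeR called 0 of 18. There were 0 at an unadjusted p under 0.05 and 0 by DESeq2, and camera gave an adjusted p of 0.461.

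Another 10 lists did not pass camera in hypoxia, 8 of them with members called in both directions. The higher and lower members numbered 10 and 9 of 29 for gluconeogenesis, urea cycle and amino acid breakdown and 5 and 9 of 20 for lipogenesis. They numbered 9 and 9 of 26 for drug metabolism and 7 and 5 of 18 for bile acid synthesis and transport. The corresponding numbers were 11 and 3 of 32 for glucocorticoid receptor targets, 5 and 3 of 21 for acute phase proteins and 2 and 6 of 20 for the cell cycle. They were 3 and 2 of 20 for the unfolded protein and integrated stress responses, or 0 and 1 adjusted over the list alone. The remaining lists had 0 and 2 of 24 for cholesterol synthesis and 1 and 0 of 14 for immediate early genes. Camera adjusted p for these 10 lists ranged from 0.07 to 1. The pyruvate carboxylase gene Pcx rose by 1.61 ± 0.07 (SE), while the lipogenic transcription factor gene Mlxipl dropped by 0.89 (edgeR adjusted p = 6.35e-06). Median, mean and test direction differed in sign for gluconeogenesis (-0.18 against a mean of 0.005) and for bile acid synthesis (0.02 against -0.03). For drug metabolism the test pointed up, with a median of -0.025 and a mean of -0.03.

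**Figure D2:**
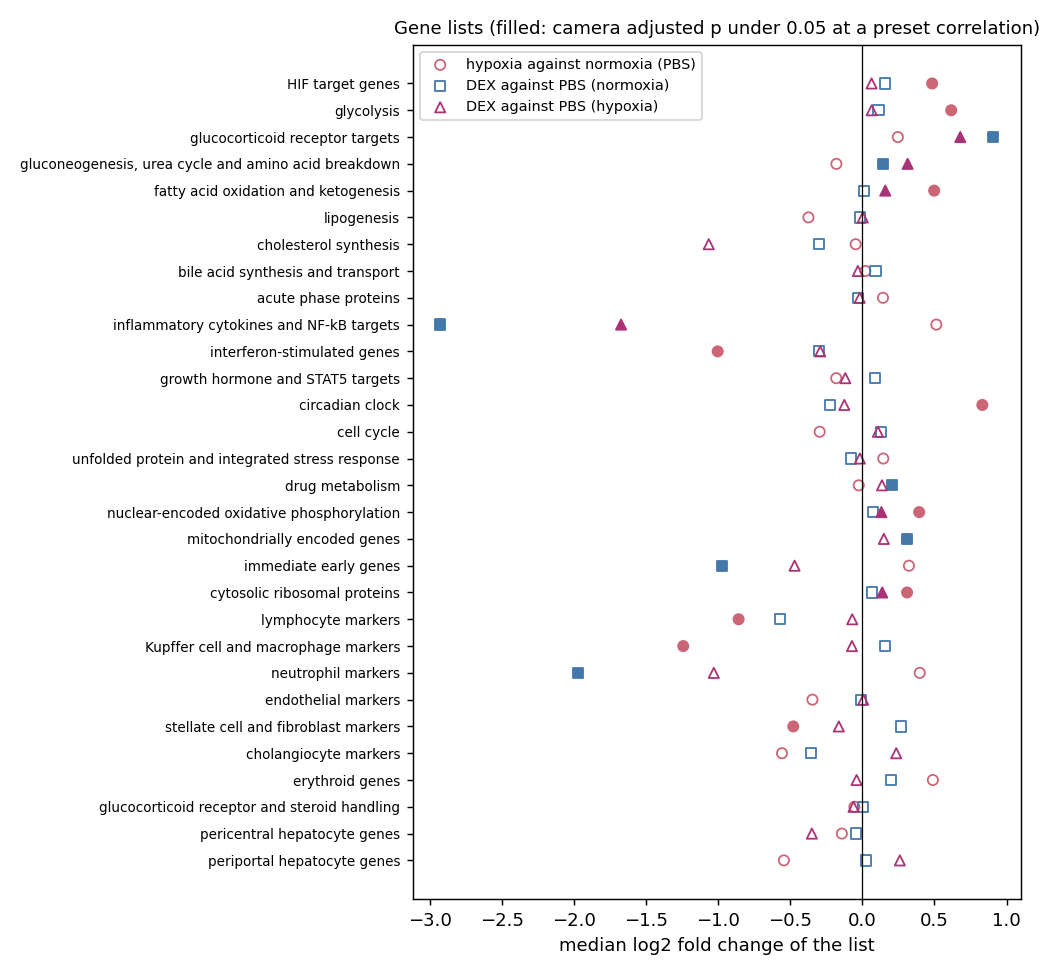
Median log2 fold change of each fixed gene list with at least 3 measured members, for hypoxia against normoxia in PBS mice (circles), DEX against PBS in normoxia (squares) and DEX against PBS in hypoxia (triangles). Filled symbols passed camera at an adjusted p under 0.05 with a preset inter-gene correlation of 0.01, and none of the 28 list calls passed with an estimated correlation.

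In normoxia, 17 of 32 glucocorticoid receptor targets rose 2 h after DEX, while 9 of 18 inflammatory and 7 of 14 immediate early genes fell. By edgeR's test, 1300 genes were higher and 1026 lower after DEX, of which 460 and 345 changed at least 2-fold. Fam107a (ENSMUSG00000021750, chromosome 14, 8296274 to 8318023) rose from 0.379 ± 0.198 CPM to 38.3 ± 6.20 CPM (log2 fold change 6.68, SE 0.35, edgeR adjusted p = 3.46e-07). Ddit4, which encodes an inhibitor of the growth kinase complex mTORC1, rose from 4.19 ± 0.459 CPM to 167 ± 30.2 CPM (log2 fold change 5.32, SE 0.29, edgeR adjusted p = 1.13e-06). The chemokine gene Ccl2 fell from 38.4 ± 21.0 CPM to 0.524 ± 0.136 CPM (log2 fold change -6.19, SE 1.07, edgeR adjusted p = 0.00449). Il1b, which encodes interleukin 1 beta, fell from 39.2 ± 12.8 CPM to 2.38 ± 0.526 CPM (log2 fold change -4.01, SE 0.48, edgeR adjusted p = 0.000418).

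Greb1 had no counts in the Normoxia_PBS libraries and 5.41 ± 3.27 CPM after DEX (edgeR adjusted p = 9.67e-05), at least 27.3-fold higher against a floor of 3 counts per library. The clock repressor gene Ciart rose by 5.42 on the log2 scale (edgeR adjusted p = 7.69e-06), Mdm1 by 4.81 (edgeR adjusted p = 4.41e-06) and Phf11c by 4.61 (edgeR adjusted p = 2.4e-10). The endothelial adhesion gene Sele fell, with a log2 fold change of -7.20 (edgeR adjusted p = 0.0389), as did the chemokine genes Cxcl10, at -6.16 (edgeR adjusted p = 0.0252), Ccl4, at -4.35 (edgeR adjusted p = 0.0152), and Cxcl11, at -4.03 (edgeR adjusted p = 0.0174). The Sele call was lost without Hypoxia_DEX-1, Hypoxia_DEX-3, Hypoxia_PBS-3, Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-2 or Normoxia_PBS-3, and without the count filter or with the near-identical pair summed (adjusted p from 3.19e-05 to 0.131 over all alternatives). The Cxcl10 call was lost without Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-2 or Normoxia_PBS-3 (adjusted p from 4.75e-07 to 0.0949 over all alternatives). Ccl4 and Cxcl11 lost their calls without Normoxia_DEX-1, Normoxia_DEX-2 or Normoxia_DEX-3, with adjusted p from 2.74e-06 to 0.0694 and from 3.18e-05 to 0.0746 over all alternatives. Cxcl10 stood at 30.7, 122 and 307 CPM in the Normoxia_PBS libraries and at 2.83, 1.70 and 1.93 CPM in the Normoxia_DEX libraries.

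Of the 32 measured glucocorticoid receptor targets, 17 rose and 1 fell, or 20 higher and 1 lower adjusted over the list alone, at a median of 0.91 (camera adjusted p = 1.6e-09, adjusted p = 0.771 with an estimated correlation). Among the fixed genes, Fkbp5, which encodes a co-chaperone of the receptor, rose from 98.5 ± 35.3 CPM to 540.4 ± 34.2 CPM (log2 fold change 2.46, SE 0.26, edgeR adjusted p = 0.000108). Tsc22d3, which encodes GILZ, rose by 1.85 ± 0.19 (SE) (edgeR adjusted p = 6.49e-05). Tat, which encodes tyrosine aminotransferase, rose by 1.56 ± 0.27 (SE) (edgeR adjusted p = 0.00265), Slc2a1 by 0.82 ± 0.14 (SE) (edgeR adjusted p = 0.000968) and Lcn2 by 2.02 ± 0.41 (SE) (edgeR adjusted p = 0.00934). Pck1 rose by 0.74 ± 0.21 (SE) (edgeR adjusted p = 0.0317). The Pck1 call was lost without Hypoxia_PBS-2, Normoxia_DEX-1, Normoxia_DEX-2 or Normoxia_DEX-3, and without the count filter, with only the compared groups in the fit or without both Hypoxia_DEX-2 and Hypoxia_PBS-1 (adjusted p from 0.00299 to 0.12 over all alternatives). Vegfa fell by 0.46 (edgeR adjusted p = 0.0247). The Vegfa call was lost without Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-2 or Normoxia_PBS-3 (adjusted p from 0.00546 to 0.107 over all alternatives). Nr3c1 at -0.12, Per1 at -0.06, G6pc at -0.68, Cpt1a at -0.16, Fgf21 at -3.16, Angptl4 at 0.20, Egln3 at -0.56, Cyp7a1 at 1.01, Mt2 at 0.69 and Hamp at -0.43 on the log2 scale did not pass (edgeR adjusted p from 0.0512 to 0.863). Mt2, a metallothionein gene, passed with RLE size factors, with DESeq2, with the replicate block, with only the compared groups in the fit and without both Hypoxia_DEX-2 and Hypoxia_PBS-1 (adjusted p = 0.0498, 0.00861, 0.0396, 0.0102 and 0.00725, from 0.00725 to 0.168 over all alternatives). Egln3 passed with the replicate block, with only the compared groups and without both those libraries (adjusted p = 0.0434, 0.0321 and 0.00924, from 0.00924 to 0.334). With 1 library left out, calls were gained by Angptl4 without Normoxia_PBS-1 (adjusted p from 0.0079 to 0.932 over all alternatives) and Hamp without Normoxia_DEX-2 (adjusted p from 0.038 to 0.365 over all alternatives), by Mt2 without Hypoxia_DEX-2, Hypoxia_PBS-1, Hypoxia_PBS-2 or Normoxia_PBS-3 and by Egln3 without Hypoxia_PBS-1. Gluconeogenesis, urea cycle and amino acid genes rose in 9 of 29 cases and fell in 2 (camera adjusted p = 0.0211, adjusted p = 0.9 with an estimated correlation). The gluconeogenesis call was lost without Normoxia_DEX-2, Normoxia_PBS-1 or Normoxia_PBS-2 (highest adjusted p = 0.126).

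Inflammatory cytokine and NF-kB target genes fell in 9 of 18 cases with 0 higher, or 0 higher and 14 lower adjusted over the list alone, at a median of -2.93 (camera adjusted p = 2.79e-07, adjusted p = 0.891 with an estimated correlation). At an unadjusted p under 0.05 edgeR had 0 of them higher and 14 lower, and DESeq2 called 0 higher and 14 lower. Tnf fell from 6.18 ± 2.80 CPM to 0.469 ± 0.0247 CPM (log2 fold change -3.71, SE 0.57, edgeR adjusted p = 0.00104). Immediate early genes, which respond first to growth and stress stimuli, fell in 7 of 14 cases and rose in 2 (camera adjusted p = 0.00311, adjusted p = 0.891 with an estimated correlation). Among them were Egr1 at -1.23 ± 0.16 (SE), Junb at -1.63 ± 0.22 (SE) and Nr4a1 at -1.75 ± 0.31 (SE). Neutrophil markers fell in 3 of 9 cases, or 6 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.891 with an estimated correlation). Csf3r had -1.33 ± 0.24 (SE) and Cxcr2 -2.11 ± 0.41 (SE). Drug metabolism genes rose in 9 of 26 cases and fell in 1 (camera adjusted p = 0.000121, adjusted p = 0.889 with an estimated correlation). Fmo5 rose from 491 ± 97.0 CPM to 2103 ± 167 CPM and Por by 1.24 ± 0.11 (SE). Mitochondrially encoded genes rose in 6 of 10 cases (camera adjusted p = 0.00286, adjusted p = 0.891 with an estimated correlation). Kupffer cell and endothelial marker medians were 0.16 and -0.01, and the endothelial gene Lyve1 rose by 2.40 ± 0.12 (SE) (edgeR adjusted p = 4.66e-08). Clock genes went both ways, 4 higher and 6 lower of 17, with Nr1d1 at -2.42 ± 0.19 (SE).

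In hypoxia, 14 of 32 glucocorticoid receptor targets rose after DEX and 5 of 18 inflammatory genes fell. By edgeR's test, 850 genes were higher and 977 lower in Hypoxia_DEX than in Hypoxia_PBS, and 222 and 234 changed at least 2-fold. With the near-identical libraries Hypoxia_DEX-1 and Hypoxia_DEX-3 summed, 644 were higher and 516 lower, and without both Hypoxia_DEX-2 and Hypoxia_PBS-1, 1249 and 1410, alternatives chosen after seeing the data. Phf11c (ENSMUSG00000091144, chromosome 14, 59380833 to 59395381) rose from 9.04 ± 1.27 CPM to 167 ± 18.8 CPM (log2 fold change 4.20, SE 0.13, edgeR adjusted p = 5.39e-10). Setdb2, a histone methyltransferase gene 6627 bp from Phf11c on the same strand, rose by 3.50 on the log2 scale (edgeR adjusted p = 7.06e-10). Fam107a rose from 0.990 ± 0.539 CPM to 21.0 ± 5.28 CPM (log2 fold change 4.42, SE 0.32, edgeR adjusted p = 1.04e-05). Il1b fell from 35.3 ± 16.6 CPM to 5.53 ± 2.72 CPM (log2 fold change -2.73, SE 0.45, edgeR adjusted p = 0.00424). The ubiquitin ligase gene Neurl3 fell from 24.6 ± 12.4 CPM to 3.17 ± 0.759 CPM (log2 fold change -2.98, SE 0.48, edgeR adjusted p = 0.00346).

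The serpin gene Serpina3c rose by 3.58 (edgeR adjusted p = 2.48e-05) and the metalloprotease gene Adamts15 by 3.26 (edgeR adjusted p = 0.000696). Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, rose by 3.52 (edgeR adjusted p = 0.014). The Pdk4 call was lost without Hypoxia_PBS-2 or Hypoxia_PBS-3 (adjusted p from 4.25e-06 to 0.0647 over all alternatives). The log2 fold change was -3.59 for Cxcl11 (edgeR adjusted p = 0.0276). The Cxcl11 call was lost without Hypoxia_DEX-1, Hypoxia_DEX-3, Hypoxia_PBS-2 or Hypoxia_PBS-3, and without the count filter, with only the compared groups in the fit or with the near-identical pair summed (adjusted p from 0.000593 to 0.114 over all alternatives). Ccl2 had -3.42 (edgeR adjusted p = 0.0332). The Ccl2 call was lost without Hypoxia_DEX-1, Hypoxia_DEX-3, Hypoxia_PBS-2, Hypoxia_PBS-3, Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3 or Normoxia_PBS-2, and without the count filter, with only the compared groups in the fit or with the near-identical pair summed (adjusted p from 0.00205 to 0.122 over all alternatives). Serpina7, which encodes thyroxine-binding globulin, had -3.17 (edgeR adjusted p = 0.0184). The Serpina7 call was lost without Hypoxia_DEX-1, Hypoxia_DEX-3, Hypoxia_PBS-2 or Hypoxia_PBS-3, and with only the compared groups in the fit or with the near-identical pair summed (adjusted p from 2.56e-07 to 0.113 over all alternatives). Gbp11, which encodes a guanylate-binding protein, had -3.04 (edgeR adjusted p = 0.017). The Gbp11 call was lost without Hypoxia_DEX-1, Hypoxia_DEX-3, Hypoxia_PBS-2 or Hypoxia_PBS-3, and with only the compared groups in the fit or with the near-identical pair summed (adjusted p from 1.73e-05 to 0.0816 over all alternatives). Hypoxia_PBS libraries spread widely for such genes: Cxcl10 stood at 36.7, 587 and 366 CPM in them and at 8.64, 50.5 and 6.41 CPM in Hypoxia_DEX. Leaving out Hypoxia_PBS-3 gave 535 higher and 557 lower genes. The lower genes numbered 470 without Hypoxia_DEX-1, 472 without Hypoxia_DEX-3 and 651 without Hypoxia_PBS-2.

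Of the 32 glucocorticoid receptor targets, 14 rose and 0 fell, or 19 higher and 0 lower adjusted over the list alone, at a median of 0.68 (camera adjusted p = 2.09e-10, adjusted p = 0.771 with an estimated correlation). Of them, 0 were lower at an unadjusted p under 0.05 and 0 by DESeq2. Ddit4 rose from 13.6 ± 5.36 CPM to 99.3 ± 17.1 CPM (log2 fold change 2.88, SE 0.26, edgeR adjusted p = 8.05e-05) and the arrestin-domain gene Arrdc2 by 1.86 ± 0.15 (SE) (edgeR adjusted p = 7.57e-06). Tat rose by 1.97 ± 0.28 (SE) (edgeR adjusted p = 0.00113) and Pck1 from 713 ± 94.2 CPM to 1578 ± 159 CPM (log2 fold change 1.15, SE 0.21, edgeR adjusted p = 0.00448). Egln3, a HIF target that encodes a prolyl hydroxylase, fell from 30.9 ± 8.40 CPM to 11.1 ± 2.78 CPM (log2 fold change -1.49, SE 0.24, edgeR adjusted p = 0.00217). Fkbp5 rose by 1.10 ± 0.25 (SE) (edgeR adjusted p = 0.0174). The Fkbp5 call was lost without Hypoxia_DEX-1, Hypoxia_PBS-2 or Hypoxia_PBS-3, and without the count filter (adjusted p from 4.18e-05 to 0.0607 over all alternatives). Vegfa dropped by 0.59 (edgeR adjusted p = 0.00946). The Vegfa call was lost without Hypoxia_DEX-1 (adjusted p from 0.00108 to 0.0525 over all alternatives). Tsc22d3 rose by 0.67 ± 0.19 (SE) (edgeR adjusted p = 0.045). The Tsc22d3 call was lost without Hypoxia_DEX-1, Hypoxia_DEX-2, Hypoxia_DEX-3, Hypoxia_PBS-1, Hypoxia_PBS-3, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-2 or Normoxia_PBS-3, and without the count filter, with only the compared groups in the fit, with the near-identical pair summed or without both Hypoxia_DEX-2 and Hypoxia_PBS-1 (adjusted p from 0.0059 to 0.123 over all alternatives). Nr3c1 dropped by 0.23 (edgeR adjusted p = 0.0469). The Nr3c1 call was lost without Hypoxia_DEX-1, Hypoxia_DEX-2, Hypoxia_DEX-3, Hypoxia_PBS-2, Hypoxia_PBS-3, Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-1 or Normoxia_PBS-2, and with RLE size factors, with DESeq2, without the count filter, with the replicate number as a block, with only the compared groups in the fit or with the near-identical pair summed (adjusted p from 0.0262 to 0.188 over all alternatives).

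Other fixed genes did not pass in hypoxia, with log2 fold changes of -0.08 for Per1, 0.66 for G6pc, 0.28 for Cpt1a, -0.99 for Fgf21, 0.12 for Angptl4, 0.13 for Slc2a1, 0.17 for Cyp7a1, 1.31 for Lcn2, 0.69 for Mt2 and -0.02 for Hamp (edgeR adjusted p from 0.06 to 0.965). Of these, Lcn2 and Mt2 passed with DESeq2 (adjusted p = 0.0152 and 0.00845, from 0.0152 to 0.272 and from 0.00845 to 0.19 over all alternatives). Lcn2 also passed with only the compared groups in the fit and Mt2 with the replicate block (adjusted p = 0.0437 and 0.0404). Lcn2 passed too without Normoxia_PBS-1 or Normoxia_PBS-3, and Mt2 without Hypoxia_PBS-2 or Normoxia_PBS-3. Gluconeogenesis, urea cycle and amino acid genes rose in 6 of 29 cases and fell in 1, or 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.891 with an estimated correlation). Aass rose by 0.82 ± 0.13 (SE). Inflammatory cytokine and NF-kB target genes fell in 5 of 18 cases with 0 higher, or 0 higher and 8 lower adjusted over the list alone, at a median of -1.67 (camera adjusted p = 5.75e-05, adjusted p = 0.891 with an estimated correlation). At an unadjusted p under 0.05 there were 0 higher and 9 lower, and by DESeq2 0 and 8. In fatty acid oxidation and ketogenesis the list moved up, with 1 of 30 members past the test (camera adjusted p = 0.0211, adjusted p = 0.9 with an estimated correlation). That call was lost without Hypoxia_DEX-2 or Hypoxia_PBS-2 (highest adjusted p = 0.552). Oxidative phosphorylation and ribosomal protein lists moved up by medians of 0.13 (camera adjusted p = 0.000176, adjusted p = 0.9 with an estimated correlation) and 0.14 (camera adjusted p = 3.01e-05, adjusted p = 0.891 with an estimated correlation), with 3 and 1 of 30 members past the test. By DESeq2 9 and 8 were higher, at an unadjusted p under 0.05 12 and 12, and adjusted over the list alone 3 and 0. Drug metabolism genes rose in 7 of 26 cases and fell in 2, without a camera call (camera adjusted p = 0.0503, adjusted p = 0.891 with an estimated correlation), and Cyp2b10 rose by 2.72 ± 0.35 (SE). Cholesterol synthesis genes had a median of -1.06 (camera adjusted p = 0.0533, adjusted p = 0.925 with an estimated correlation), but edgeR called 0 of 24, with 2 lower at an unadjusted p under 0.05 and 1 by DESeq2. Kupffer cell, neutrophil and lymphocyte marker medians were -0.07, -1.03 and -0.07, none past camera (adjusted p = 0.891, 0.0828 and 0.688).

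The DEX responses at the 2 oxygen levels were mostly alike in direction and, for a set of induced genes, smaller in hypoxia. Of the genes called in both, 555 rose and 470 fell at both oxygen levels, against 79.7 and 72.3 for independent lists. The correlation of the responses across all genes was 0.677, from groups that share no library (genes are not independent replicates). The 1300 genes raised in normoxia had a median log2 fold change of 0.72 there and 0.37 in hypoxia. Chosen the other way round, the 850 genes raised in hypoxia had medians of 0.64 in hypoxia and 0.59 in normoxia. The 1026 genes lowered in normoxia had medians of -0.76 and -0.50, and the 977 lowered in hypoxia -0.67 in hypoxia and -0.44 in normoxia. A median over genes picked by a call is biased upward in size in the condition that was used to pick them.

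Tested as an interaction, the signed DEX response was lower in hypoxia for 138 genes and higher for 45, a weaker fall counting as higher. With the near-identical pair summed these counts were 51 and 19, and all 70 genes were among the 183. Of the 138, 121 rose with DEX in normoxia, while in hypoxia 41 rose and 28 fell, and their median DEX effect was 1.02 in normoxia and 0.07 in hypoxia. Picking genes by the interaction itself favours such a contrast, so these medians can overstate the difference. Of the 45, 33 fell with DEX in normoxia and 1 rose, while in hypoxia 5 fell and 15 rose. Ddit4 was induced by 5.32 on the log2 scale in normoxia and 2.88 in hypoxia (interaction -2.44 ± 0.36 (SE), edgeR adjusted p = 0.0123). Tcim (ENSMUSG00000056313, chromosome 8, 24437180 to 24438984) rose from 12.3 ± 1.74 CPM to 117 ± 14.0 CPM in normoxia and from 17.2 ± 4.66 CPM to 36.9 ± 6.50 CPM in hypoxia (interaction -2.16 ± 0.27 (SE), edgeR adjusted p = 0.00325). The kinase gene Sgk1, a glucocorticoid receptor target, stood at 43.4 ± 12.1 CPM and 129.5 ± 15.2 CPM in normoxia and at 64.3 ± 3.29 CPM and 63.4 ± 8.37 CPM in hypoxia, in PBS and DEX (interaction -1.60 ± 0.25 (SE), edgeR adjusted p = 0.0123). Rgs16, a regulator of G protein signalling, had responses of 2.96 and 0.94 (interaction -2.03 ± 0.31 (SE), edgeR adjusted p = 0.0123). Gadd45g had responses of 1.42 and 0.17 (edgeR adjusted p = 0.00296) and the monooxygenase gene Fmo5 of 2.10 and 0.78 (edgeR adjusted p = 0.00296). The baseline of these genes under PBS also differed between oxygen levels. Log2 fold changes of hypoxia against normoxia there were 3.924 for Rgs16, 1.695 for Ddit4, 1.332 for Fmo5 and 1.294 for Gadd45g. They were 0.568 for Sgk1 and 0.492 for Tcim. A smaller response in hypoxia can therefore go with a higher level before DEX.

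Among genes with a higher response in hypoxia, the transcription factor gene Klf10 was lowered by DEX in normoxia, at -2.19, and had -0.24 in hypoxia (interaction 1.95 ± 0.29 (SE), edgeR adjusted p = 0.00875). The MYC antagonist gene Mnt had -1.63 and -0.09 (interaction 1.54 ± 0.18 (SE), edgeR adjusted p = 0.00142). The kinase gene Plk3 had -0.86 and 0.91 (interaction 1.76 ± 0.24 (SE), edgeR adjusted p = 0.00454). Klf10, Plk3, Mnt, Ddit4, Tcim, Rgs16, Gadd45g, Sgk1 and Fmo5 kept their calls with the pair summed and without any 1 of the 12 libraries. The interaction was 3.98 for Fbf1, 2.82 for the ephrin gene Efna1, 2.41 for Osgin1, -2.53 for Treh, -2.36 for Fam89a and -2.03 for the lipogenic gene Thrsp (edgeR adjusted p from 0.0208 to 0.0372). It was -0.47 for Clock, -0.65 for Hlf, -1.20 for the glutathione transferase gene Gstm2 and -0.68 for Cyp3a11 (edgeR adjusted p from 0.0314 to 0.036). These 10 calls were lost with the pair summed, and each was lost without Hypoxia_DEX-1 or without Hypoxia_DEX-3. With the replicate number as a block the calls of Fbf1, Efna1, Clock and Hlf were lost, without the count filter those of Efna1, Thrsp, Clock and Gstm2, and without both Hypoxia_DEX-2 and Hypoxia_PBS-1 those of Fbf1, Efna1, Osgin1, Thrsp, Hlf and Gstm2. Each of the other libraries, left out alone, ended between 3 and 9 of the 10, with adjusted p up to 0.137.

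None of the fixed genes reported here passed the interaction test of edgeR (edgeR adjusted p from 0.0667 to 1). The values nearest the threshold were -1.18 ± 0.27 (SE) for Tsc22d3 and -1.35 ± 0.35 (SE) for Fkbp5 (edgeR adjusted p = 0.0667 and 0.117). DESeq2 called both lower (adjusted p = 0.00166 and 0.00347, from 0.00166 to 0.193 and from 0.00347 to 0.301 over all alternatives). Egln3 at -0.93 passed without both Hypoxia_DEX-2 and Hypoxia_PBS-1 (adjusted p = 0.00668, from 0.00668 to 0.585). With single libraries left out, Egln3 passed without Hypoxia_PBS-1, Tsc22d3 without Hypoxia_PBS-3 and Slc2a1 without Normoxia_PBS-3 (adjusted p from 0.0406 to 0.325 over all alternatives). Glucocorticoid receptor targets as a list had 1 higher and 3 lower of 32, or 2 higher and 7 lower adjusted over the list alone, at a median of -0.04 (camera adjusted p = 0.244, adjusted p = 0.9 with an estimated correlation). Drug metabolism genes moved down, with 4 of 26 past the test, at a median of -0.24 (camera adjusted p = 0.0211, adjusted p = 0.891 with an estimated correlation). The drug metabolism call was lost without Hypoxia_PBS-2, Normoxia_DEX-2, Normoxia_PBS-1 or Normoxia_PBS-2 (highest adjusted p = 0.126). Lymphocyte markers, with a median DEX effect of -0.57 in normoxia (5 of 14 lower and 1 higher) and -0.07 in hypoxia, moved up by a median of 0.48 (camera adjusted p = 0.00926, adjusted p = 0.889 with an estimated correlation). So did inflammatory genes by 1.13 (camera adjusted p = 0.0361, adjusted p = 0.9 with an estimated correlation). The inflammatory list call was lost without Hypoxia_DEX-2, Hypoxia_PBS-1, Normoxia_DEX-1, Normoxia_DEX-2, Normoxia_DEX-3, Normoxia_PBS-2 or Normoxia_PBS-3 (highest adjusted p = 0.723) and with RLE size factors (adjusted p = 0.051). Without both Hypoxia_DEX-2 and Hypoxia_PBS-1 the inflammatory list turned down (camera adjusted p = 0.348). Neutrophil markers had a median of 0.82 without a camera call (camera adjusted p = 0.054, adjusted p = 0.9 with an estimated correlation), and 0 of 9 passed by edgeR, by DESeq2 or at an unadjusted p under 0.05. Ribosomal protein genes moved up by 0.06 (camera adjusted p = 0.0284, adjusted p = 0.9 with an estimated correlation). The ribosomal call was lost without Hypoxia_DEX-2, Hypoxia_PBS-3, Normoxia_DEX-1 or Normoxia_PBS-1 (highest adjusted p = 0.113). In the inflammatory, lymphocyte and ribosomal lists edgeR called 0 genes either way, with 3, 3 and 0 higher and none lower at an unadjusted p under 0.05 and 0 by DESeq2. The interaction counts moved with single libraries: the 138 became 50 without Hypoxia_DEX-1, 46 without Hypoxia_DEX-3, 91 without Hypoxia_PBS-2, 59 without Normoxia_DEX-2, 62 without Normoxia_DEX-3, 72 without Normoxia_PBS-1, 67 without Normoxia_PBS-2 and 213 without Hypoxia_PBS-1. In addition, 322 lower and 153 higher genes were called without both Hypoxia_DEX-2 and Hypoxia_PBS-1. The 45 became 20 without Hypoxia_DEX-1, 17 without Hypoxia_DEX-3, 24 without Normoxia_DEX-2, 29 without Normoxia_PBS-1, 26 without Normoxia_PBS-2 and 93 without Hypoxia_PBS-1.

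**Figure D3:**
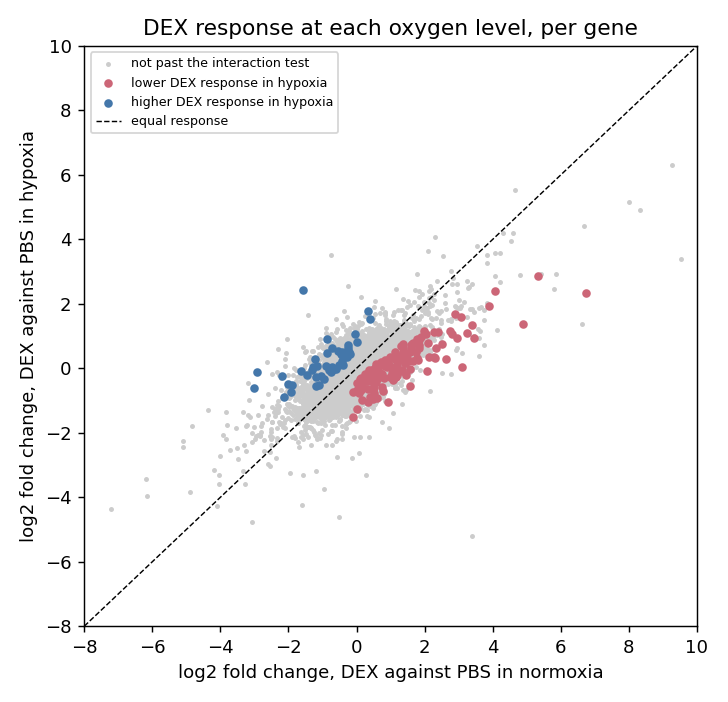
Log2 fold change of DEX against PBS in normoxia (horizontal) and in hypoxia (vertical), 1 point per tested gene. Red points mark the 138 genes with a lower DEX response in hypoxia and blue points the 45 with a higher one by the interaction test, and the dashed line marks equal responses. Responses are signed, so a weaker fall counts as higher.

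**Figure D4:**
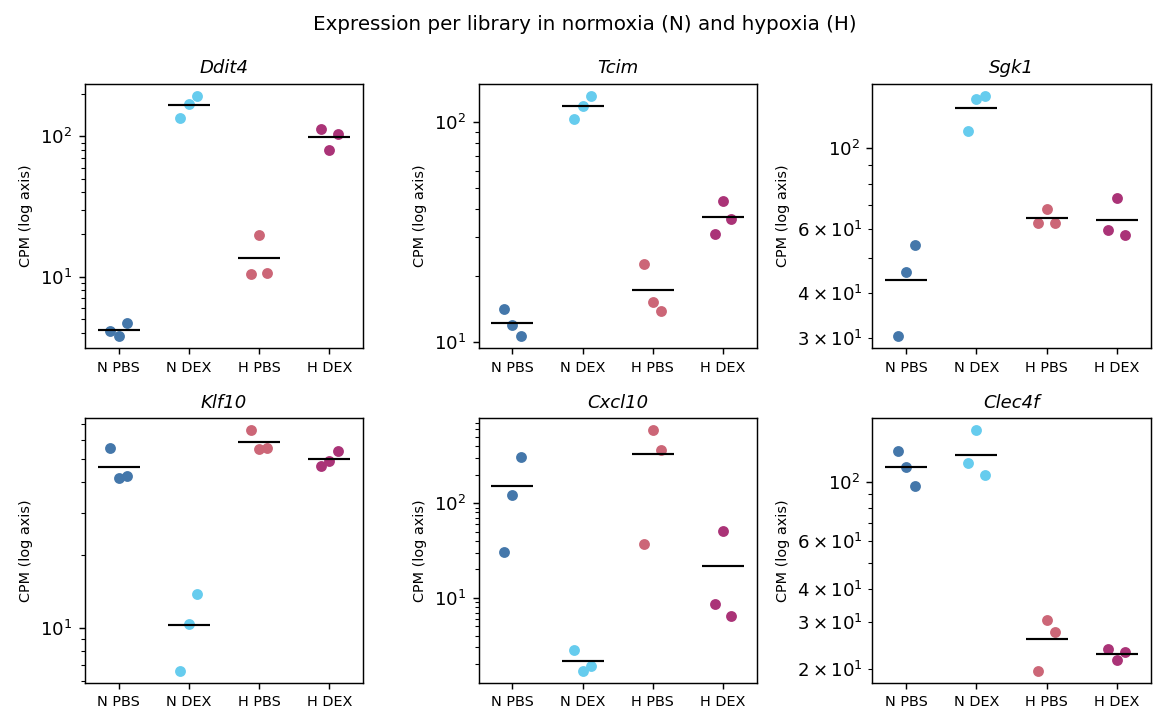
Expression of 6 genes in each of the 12 libraries (CPM, log axis), with horizontal bars at the mean of n = 3 libraries, for normoxia (N) and hypoxia (H). Ddit4, Tcim, Sgk1 and Klf10 passed the interaction test, Cxcl10 varied widely among PBS libraries, and Clec4f, a Kupffer cell marker, was lower in all 6 hypoxia libraries than in the 6 normoxia libraries.

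The hypoxia effect was also measured between the DEX groups. By edgeR's test 2865 genes were higher and 3078 lower in Hypoxia_DEX than in Normoxia_DEX, and with the near-identical pair summed 2577 and 2435. Shared with the PBS comparison were 1920 higher and 1761 lower genes, against 541.1 and 518.5 for independent lists. Of the 138 genes with a lower DEX response in hypoxia, 101 were lower in hypoxia under DEX, while 57 were higher in hypoxia under PBS. Kupffer cell markers had a median log2 fold change of -1.28 under DEX and -1.24 under PBS, and neutrophil markers 1.21 and 0.40.

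The hypoxia effect and the DEX effect in normoxia, which share the Normoxia_PBS libraries, overlapped in 371 genes higher and 202 lower in both, against 245.5 and 172.8 for independent lists. Opposite calls numbered 171 for genes lower in hypoxia and higher with DEX (219.0 for independent lists) and 160 for the converse (193.8). Unchanged groups simulated against those shared controls gave 0 shared higher and 0.02 shared lower calls on average. With no gene changed almost none is called, so these values cannot show how many shared calls the controls add among changed genes. Across genes, which are not independent replicates, the correlation of fold changes was 0.162. The 50 simulations of unchanged groups gave 0.501 from the shared controls alone. Simulated fold changes hold noise only, so these correlations do not decide whether the effects are alike. The covariance was 0.075 against a simulated 0.029, a difference of 0.046. The 3 control libraries could not be split into parts of at least 2, so part of the overlap above independence can come from the shared controls.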

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

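The tests on Hypoxia_DEX-2, on the near-identical pair, on the selection of genes, on the baseline, on the hepatocyte share and on expression per Kupffer cell were chosen only after the result was seen.

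The DEX response was lower in hypoxia for 138 genes and higher for 45 by the interaction test of edgeR. Hypoxia_DEX-2, with its low score on the second component, is not excluded as a cause, although the effect sizes below go against it as the whole cause. Over the 1300 genes raised in normoxia, the median DEX effect in hypoxia was 0.372, 0.381 and 0.372 in Hypoxia_DEX-1, Hypoxia_DEX-2 and Hypoxia_DEX-3. These values argue against a weak induction in Hypoxia_DEX-2 for those genes. Over the 1026 genes lowered in normoxia the medians were -0.487, -0.428 and -0.483. The 104 lower responses called without Hypoxia_DEX-2 rest on the near-identical libraries Hypoxia_DEX-1 and Hypoxia_DEX-3 alone. Their spread can be too small. With that pair also summed, 1 library was left, assumed to vary like the other groups. The median interaction of the 138 genes was then -0.964, against -0.966 in all libraries. These genes were picked with the remaining libraries too, which favours a near-equal median. The near-identical pair is not the whole cause, since 51 lower responses were called with it summed and Hypoxia_DEX-2 kept, although fewer genes passed. Selection of genes on their normoxia response would act both ways, but 121 induced genes responded less in hypoxia and 15 responded less in normoxia. For genes lowered by DEX the numbers were 33 and 28, so selection is not excluded there. Of 100 drawn splits within the oxygen levels, 7 called as many genes as the real 183, so chance is not excluded by that count: the highest other, 3540, exchanged the DEX and PBS labels at 1 oxygen level, 5 more kept the true DEX split at 1 level only, and the 80 splits mixed at both levels called at most 16, so the large counts follow the structure of the DEX effect. A baseline raised in hypoxia, with an equal level after DEX, is not excluded. Of the 138 genes, 101 were called lower in hypoxia under DEX (93 with the pair summed), which goes against an equal level for those genes. However, the 138 were picked with the same libraries, and picking by a lower interaction itself favours lower levels under DEX. Under PBS, 57 of the 138 were called higher in hypoxia, against 2618 of all 13861 tested genes. For those 57 a raised baseline may contribute. The other 81 were not called higher, which does not show an unraised baseline. The median hypoxia effect of the 138 was 0.245 under PBS and -0.686 under DEX. An effect of oxygen on glucocorticoid receptor activity may explain the weaker induction and was not tested. The list of 32 receptor targets did not shift as a whole in the interaction (median -0.036, camera adjusted p = 0.244). In it 3 members were lower and 1 higher, or 7 and 2 adjusted over the list alone.

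Kupffer cell markers fell in hypoxia by a median of 1.24 on the log2 scale. A larger hepatocyte share would lower the markers of all other cells alike, but the Kupffer cell median lay below the endothelial one by a difference of -0.896 (two-sided permutation test over genes, p = 0.00031, genes not being independent replicates). By the same permutation test the differences were -0.685 (p = 0.00383) against cholangiocyte, -0.763 (p = 0.0132) against stellate cell, -1.64 (p = 0.00032) against neutrophil and -0.383 (p = 0.0513) against lymphocyte markers, the last not past 0.05. The permutation treats genes as independent and does not measure variation between animals. The Kupffer cell list had an estimated inter-gene correlation of 0.701, so these p-values can be too small. The differences of medians go against a larger hepatocyte share as the whole cause but do not exclude it. Part of the fall, of the size of the endothelial median of -0.35, may follow from it. Lower expression per cell and fewer cells cannot be told apart in bulk RNA: log2 fold changes ranged over 2.057, from Folr2 at -2.25 to Cd163 at -0.20, which either might give. A loss of Kupffer cells or a change of their state in hypoxia stays open as a hypothesis.

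Ribosomal protein and oxidative phosphorylation genes rose in hypoxia by medians of 0.31 and 0.39. Short, abundant transcripts could rise through a bias of length or expression, but among 10000 random lists matched on both, the ribosomal median stood at percentile 99.05 (matched median 0.11, limits -0.10 to 0.28) and the oxidative phosphorylation median at 99.91 (matched median 0.13, limits -0.08 to 0.30). Part of each shift may follow length and expression, but the matched medians do not measure its size. Only the members of the list itself were kept out of the matched genes. Other ribosomal protein and oxidative phosphorylation genes could therefore be among them. Matched genes were also drawn independently, while the lists had estimated inter-gene correlations of 0.37 (ribosomal) and 0.577 (oxidative phosphorylation), so the limits can be too narrow. Neither list call held with an estimated correlation (adjusted p = 0.889 and 0.891), and a response to hypoxia remains a hypothesis.

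For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and in each the real split alone, 1 of 10, reached its count. Hypoxia against normoxia called 4953 genes under PBS and 5943 under DEX, and the highest other splits called 1 and 0. DEX against PBS called 2326 genes in normoxia and 1827 in hypoxia, and the highest other splits called 0 and 414. The 414 came from the split that exchanged Hypoxia_DEX-2 with Hypoxia_PBS-1, and every other wrong split of these libraries called 0. On the second component these libraries scored 9.22 and -6.36, between the other libraries of their groups. Results for DEX in hypoxia and for the interaction depend on both.

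Single genes that differed in their DEX response between the oxygen levels by edgeR's interaction test had these log2 differences, hypoxia minus normoxia: Fbf1 3.98, Efna1 2.82, Osgin1 2.41, Klf10 1.95, Plk3 1.76, Mnt 1.54, Treh -2.53, Ddit4 -2.44, Fam89a -2.36, Tcim -2.16, Thrsp -2.03, Rgs16 -2.03, Gadd45g -1.25, Sgk1 -1.60, Clock -0.47, Hlf -0.65, Fmo5 -1.32, Gstm2 -1.20 and Cyp3a11 -0.68. The calls of Fbf1, Efna1, Osgin1, Treh, Fam89a, Thrsp, Clock, Hlf, Gstm2 and Cyp3a11 were lost with the near-identical pair summed. Camera adjusted p for the interaction was 0.0361 for inflammatory genes, 0.0211 for drug metabolism, 0.0284 for ribosomal proteins and 0.00926 for lymphocyte markers, and all 4 were lost with an estimated correlation (adjusted p from 0.889 to 0.9).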

How the results depend on the processing

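The summed pair, alone or with Hypoxia_DEX-2 left out, and the joint removal of Hypoxia_DEX-2 and Hypoxia_PBS-1 were chosen after seeing the data. Counts for hypoxia against normoxia and for DEX in normoxia stayed within 1.5 times under every alternative run. For DEX in hypoxia, lower genes numbered 572 with only the groups compared in the fit and 516 with the pair summed, against 977. Interaction genes, 45 higher and 138 lower, numbered 115 and 256 with DESeq2, 85 and 175 without the count filter, 19 and 51 with the pair summed, 8 and 34 with Hypoxia_DEX-2 also left out, and 153 and 322 without both Hypoxia_DEX-2 and Hypoxia_PBS-1, where 154 of the 475 were among the 183. The cause was not tested except that summing leaves fewer samples. The median DEX effect in hypoxia of genes raised in normoxia, 0.37, was 0.388 with RLE size factors, 0.405 with DESeq2, 0.442 without the filter, 0.449 with the pair summed and 0.394 without both libraries. That of lowered genes was -0.50. The correlation of the hypoxia and DEX effects, 0.162, was 0.333 with DESeq2 and 0.382 without the filter. Leaving out 1 library at a time gave 2010 to 2604 higher and 1791 to 2490 lower genes for hypoxia under PBS, 962 to 1399 and 718 to 1349 for DEX in normoxia, 535 to 1215 and 470 to 1251 for DEX in hypoxia, 17 to 93 and 46 to 213 for the interaction, and 2431 to 3255 and 2315 to 3139 for hypoxia under DEX. The medians ranged from 0.381 to 0.482 and from -0.565 to -0.443, and the correlation from 0.118 to 0.234. Of the 245 called values of named genes, 3 were lost with RLE, 30 without the filter, 35 with the pair summed, 21 without both libraries and 68 without at least 1 library (at most 41, without Hypoxia_DEX-1). DESeq2 lost 3 of 244, and only the groups compared 30 of 226. Of 12 correlations of same-numbered deviations, 3 exceeded 0.1 (range -0.074 to 0.390). Differently numbered libraries were not compared, so these values do not decide whether the replicate numbers pair the libraries. The replicate block gave 48 and 132 interaction genes, 859 and 993 for DEX in hypoxia, and lost 13 named calls. Fgf21 in hypoxia under PBS turned from -0.05 to 3.59 on the log2 scale without Normoxia_PBS-1 (edgeR adjusted p = 0.0236, fold changes from -0.67 to 3.59 over single libraries left out), and the inflammatory list in the interaction turned down without both libraries (camera adjusted p = 0.348, range over alternatives 0.000191 to 0.9). The cause was not tested. All 28 list calls were lost with an estimated correlation, while with RLE 1 was lost. At this depth the simulated interaction test recovered 11.9% of 1.5-fold differences.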

Other observations

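No test in this part was chosen after its result was seen, and the values given per library were picked for their spread.

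Genes of the liver zones changed in part. Of 16 pericentral hepatocyte genes, 5 fell and 1 rose with DEX in normoxia and 5 fell and 0 rose in hypoxia, without a camera call (adjusted p = 0.308 and 0.0926). The Wnt pathway genes Lgr5 and Rnf43 had log2 fold changes of -2.10 and -1.62 in normoxia (edgeR adjusted p = 0.000208 and 0.000327) and of -1.84 and -2.14 in hypoxia (edgeR adjusted p = 0.000794 and 7.73e-05). Hypoxia lowered Cyp1a2, a pericentral enzyme gene, from 589 ± 115 CPM to 173 ± 34.8 CPM (log2 fold change -1.77, SE 0.16, edgeR adjusted p = 9.91e-06), and the periportal gene Gls2 from 420.1 ± 85.4 CPM to 133 ± 27.2 CPM (log2 fold change -1.65, SE 0.15, edgeR adjusted p = 8.84e-06). Periportal genes as a list had 3 higher and 7 lower of 15 (camera adjusted p = 0.0833).

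Growth hormone and STAT5 targets had 4 higher and 4 lower of 15 in hypoxia (camera adjusted p = 0.797), with a median of -0.18 and a mean of 0.25. Cyp2d9 rose from 25.7 ± 0.0697 CPM to 185 ± 19.3 CPM (log2 fold change 2.84, SE 0.18, edgeR adjusted p = 1.26e-06), and Cyp4a12a, whose reads can be shared with its near-identical neighbour Cyp4a12b, rose by 3.36 (edgeR adjusted p = 0.00536). Among 15 genes of steroid handling, 2 rose and 4 fell in hypoxia (camera adjusted p = 0.429). Serpina6, which encodes corticosteroid-binding globulin, fell from 324 ± 73.2 CPM to 50.3 ± 11.7 CPM (log2 fold change -2.69, SE 0.27, edgeR adjusted p = 6.96e-05), and Hsd11b1, which regenerates active glucocorticoid, dropped by 0.42 (edgeR adjusted p = 0.0073).

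Inflammatory transcripts varied among libraries of 1 group. Irf1 stood at 89.7, 235 and 476 CPM in Normoxia_PBS, 192, 589 and 546 CPM in Hypoxia_PBS, and 46.6, 223 and 49.5 CPM in Hypoxia_DEX, in replicate order. In Normoxia_DEX it varied little, at 18.6, 17.4 and 17 CPM. The leukocyte gene Ptprc stood at 25.9, 31.3 and 28.2 CPM in Normoxia_PBS and at 10.0, 20.7 and 16.0 CPM in Hypoxia_PBS.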
